A study of Homo sapiens with 2 samples.

How the data were processed

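Gene expression was measured in IMR-90-ER:Ras cells, human embryonic lung fibroblasts (IMR-90) that carry an oestrogen receptor-Ras fusion which 4-hydroxytamoxifen (OHT) switches on. Per the labels' protocols, cells were grown in medium with 10% serum for 6 days with or without OHT and were then transfected 3 times, 2 days apart, with small interfering RNA (siRNA) against FZR1 (also called CDH1, an activator of the anaphase-promoting complex, APC/C) or with a control siRNA. Total RNA was amplified with an amino allyl kit and hybridised to a 2-colour Toray 3D-Gene human chip, described in the labels as holding 25000 genes. There were 2 arrays. One compared FZR1-depleted OHT-treated (senescent) cells with control-siRNA senescent cells, and the other compared control-siRNA cells without OHT (proliferating) with the same kind of senescent cells. The labels number the control siRNA of the proliferating cells differently from that of the senescent cells. If the oligos differ, oligo and growth state change together for every gene on that array. The senescent RNA carried Cy5 on both arrays and the other RNA carried Cy3, so no dye swap was available.

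The deposited table holds 1 log ratio, taken here as log2, per probe and array for 24460 probes. Per the labels and the table itself, neither the log base, the direction, the scanner, the background correction nor the normalization method was stated, and the genome build is not given in the sources used here. The column medians were -6e-06 and 1.6e-05, so the authors' values were already centred on the median of each array. The base was taken as 2, and all folds below rest on that. Direction was taken from the sample titles and the design text, which both name the FZR1-depleted or proliferating RNA first and the senescent RNA as comparator. A positive value is therefore read as higher in the first-named RNA, and this direction is likely rather than stated. The FZR1-depleted array had values for 15710 probes and 8750 null cells, and the proliferating array had values for 20252 probes and 4208 null cells. The rule behind the null cells is not given in the sources used here. Spot intensities were not used here, so the signal behind each ratio is unknown.

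Gene symbols came from the platform annotation table, which gives 1 symbol for 20236 probes, several symbols for 0 probes and none for 4224 probes. Older symbols of 2960 probes were updated through a RefSeq gene table (GRCh38.p14), 17238 probes already had a current symbol, and 38 probes kept the symbol of the annotation table. No coordinates are given, since the chip's annotation names no build. The log ratios of probes of one gene were averaged, which gave 17559 genes, of which 12169 had a value on the FZR1-depleted array, 15111 on the proliferating array and 12114 on both.

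Each comparison rests on 1 array, so no p-value, SD between replicates or test of a difference could be computed, and every value describes these arrays. Before the data were examined, a size of 2-fold was fixed as the threshold for counting genes, and 32 gene lists were fixed for pathways, cell types and complexes. For each list the median log2 ratio of its measured members was computed with an exact 95% order-statistic interval over members. The median was also placed among the medians of 10000 random gene lists of the same size drawn from the genes measured on that array. These lists were not matched on signal, since the table holds none. If list members were random draws of genes, about 3.2 of the 64 list medians would lie outside the central 95% of random lists, and 33 did. Members of a list are not random draws and some lists share genes, so these numbers are not a test. The interval covers the spread over genes, not between cultures. In simulated lists drawn from the real values, the interval held the true median in 95.5% (FZR1-depleted array, 12169 genes) and 95.6% (proliferating array, 15111 genes) of draws. Simulated lists of 25 genes shifted by 0.5 upwards were recovered in 93 and 98 of 100 draws on the 2 arrays, and lists shifted by 0.5 downwards in 97 and 94. All simulated lists were random draws of genes. Their results check the calculation, not how the lists of related genes vary between cultures.

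The only internal measure of error was the spread between probes of one gene. Its pooled SD was 0.38 on the FZR1-depleted array (1367 genes with 2 or more measured probes) and 0.44 on the proliferating array (1867 genes). Of the 238 such genes with a probe past 2-fold on the FZR1-depleted array, 69 had all probes past 2-fold in the same direction. On the proliferating array this held for 99 of 327 genes. Single-probe genes near the threshold are therefore uncertain.

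Genes were named by a rule fixed before the data were examined. It takes FZR1, the 10 highest and 10 lowest genes of each array, up to 4 members of each list with the largest absolute value on the array described, a fixed set of senescence and cell-cycle genes, and the 10 genes past 2-fold on both arrays whose smaller absolute value was largest, in the same and in opposite directions. Both arrays were compared with senescent control RNA of the same label, and whether it was 1 extract is not given in the sources used here. Genes past 2-fold on both arrays were therefore set beside the number that independent lists give and beside 100 simulations. These kept each array's own values and set the correlation of their ranks, taken as normal scores, to 0.5. Two-array ratios that share 1 senescent RNA have this correlation if 3 RNAs of equal spread vary independently. RNA levels themselves were not simulated, so the simulated values rest on that setting and on normal scores. The simulated values apply only if the extract was shared. Alternatives were another centring (all probes, or a housekeeping list), the most extreme probe per gene, genes measured on both arrays, thresholds of 1.5-fold and 3-fold, scaling both arrays to one robust SD, a 10% trimmed mean, correlations without cell-cycle or extreme genes and, chosen after seeing the data, a natural logarithm and the FZR1-depleted array alone turned in direction. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.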

Results

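Transcript levels were compared across 3 kinds of RNA from IMR-90-ER:Ras fibroblasts: senescent cells with a control siRNA, senescent cells depleted of FZR1, and proliferating cells with a control siRNA that the labels number differently. Each of the last 2 was hybridised once against senescent RNA, so each comparison had n = 1 array and no replicate. Values are log2 ratios to the senescent RNA, and folds are sizes of these ratios. Their direction is likely rather than stated, from the titles and the design text, and the opposite direction on an array would exchange its higher and lower genes. The number of arrays limits the precision. The pooled SD between probes of one gene was 0.38 on the FZR1-depleted array and 0.44 on the proliferating array, and it covers measurement on one array only. Intervals given for gene lists are 95% order-statistic intervals of the median over list members.

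FZR1, the target of the siRNA, was lower in the depleted cells by a log2 ratio of -0.48, a 1.39-fold difference read from 1 probe. On the proliferating array FZR1 was at -0.09. With a pooled SD between probes of 0.38 and 1 probe for this gene, the array gives only a weak check of the depletion.

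The first comparison asked how senescent cells differed from proliferating ones. The proliferating cells had no OHT, so senescence, Ras activation and OHT itself change together on this array and cannot be told apart. Secreted inflammatory factors were far lower in proliferating cells. CXCL5 was 398-fold lower, CXCL8 (interleukin 8) 304-fold, IL1B 259-fold, CCL20 242-fold, CXCL2 228-fold, CXCL1 130-fold, CXCL3 85.6-fold and IL6 33.8-fold. The stromelysin MMP3 was 324-fold lower and the collagenase MMP1 43.6-fold lower, with both MMP1 probes in accord at -5.61 and -5.28. IL1A was 15.2-fold lower, whereas CCL2 was at -0.35. In all, 1117 of 15111 genes were at least 2-fold higher in proliferating cells and 617 were at least 2-fold lower.

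Of the 24 measured cytokines and chemokines of the senescence-associated secretory phenotype (SASP), 14 were at least 2-fold lower in proliferating cells, 2 were at least 2-fold higher and the median was -2.09 (interval -6.42 to -0.35). SASP growth factors and proteases were more mixed, with 13 of 26 lower and 6 higher (median -0.85, -2.53 to 0.36). ANGPTL4 at -4.50 and SERPINB2 at -4.39 were among the lowest of this list. NF-kB target genes had 15 of 26 lower and 3 higher, with a median of -1.20 (-1.54 to -0.61). Among them BCL2A1, a survival factor of the BCL2 family, was 206-fold lower, the prostaglandin synthase PTGS2 132-fold lower, and complement C3 at -3.81. Ras-MAPK response genes had 15 of 31 lower and 0 higher (median -0.91, -1.65 to -0.29). These included the growth factors EREG at -2.87 and HBEGF at -2.47 and the MAP kinase phosphatases DUSP4 at -2.72 and DUSP5 at -2.19. HRAS itself was at -1.30. The medians of the 4 lists lay below those of all 10000 random lists.

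Cell-division genes were higher in proliferating cells. In the G2/M and mitosis list, 40 of 44 genes were at least 2-fold higher and none was 2-fold lower (median 1.70, 1.60 to 1.84). TOP2A, a DNA topoisomerase of dividing cells, was at 2.63, MKI67 at 2.58, DLGAP5 at 2.58, NUF2 at 2.34 and the mitotic kinase CDK1 at 2.10. CCNA2 was at 1.65, CCNB1 at 1.40, PLK1 at 1.69 and AURKA at 0.53. Known substrates of APC/C-Cdh1 had 29 of 40 genes higher (median 1.28, 1.08 to 1.59), among them ANLN at 2.67, NEK2 at 2.46, SKP2 at 1.08 and GMNN at 1.14. The substrate and G2/M lists share 16 genes. DNA replication and G1/S genes had 12 of 43 higher (median 0.68, 0.56 to 0.87), led by MCM10 at 1.74 and GINS4 at 1.68. Homologous recombination and Fanconi genes had 8 of 19 higher (median 0.74, 0.38 to 1.25), led by BARD1 at 2.11. These 4 medians lay above those of all 10000 random lists. Subunits and regulators of the APC/C had 6 of 21 higher and a median of 0.45 (-0.04 to 1.12), led by BUB1B at 1.86 and FBXO5 at 1.43. All 6 were regulators or substrates, and no subunit of the complex in this list was past 2-fold, with CDC23 the highest at 0.64. The list shares 3 genes with the G2/M list and 3 with the substrate list.

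Fibroblast matrix and contractile genes were also higher in proliferating cells. Decorin (DCN) was 18.1-fold higher, COL3A1 17.1-fold and COL1A2 15.7-fold. EFEMP1, a fibulin-family matrix protein, was the highest of the named genes at 31.2-fold. TNFSF4 was 28.4-fold higher, MGARP 22.1-fold, SRGN 21.7-fold, MATN2 20.7-fold, TMEM176B 19.2-fold and ANO4 15.4-fold. Collagens and fibrillar matrix genes had 18 of 36 higher and 2 lower (median 0.96, 0.54 to 1.96). Contractile and myofibroblast genes had 10 of 17 higher and none 2-fold lower (median 1.08, 0.81 to 2.42), with smooth muscle actin ACTA2 at 2.99, LMOD1 at 2.94, ACTG2 at 2.67 and TAGLN at 2.47. Fibroblast identity genes, 5 of which are also in the collagen list, had 10 of 20 higher (median 1.16, 0.39 to 1.94). Interferon response genes had 10 of 35 higher and 1 lower (median 0.74, 0.35 to 0.98). IFIT1 was at 2.28, IFIT3 at 1.87, IFI44L at 1.86 and MX2 at 1.64, whereas the chemokine CXCL10 was at -1.45.

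Regulators of senescence differed in direction. The CDK inhibitor CDKN2B was 3.32-fold lower in proliferating cells and CDKN1A (p21) was at -0.38. CDKN1B was at 1.41, CDKN2C at 1.38 and the nuclear lamin LMNB1 at 1.34, while CDKN2A had no value on either array. The list of senescence cell-cycle inhibitors, which also holds LMNB1 and the lysosome gene GLB1, had a median of 0.69 (-0.24 to 1.38, 13 genes). p53 target genes had a median of -0.0042 (-0.23 to 0.29) and a mean of 0.01, with 1 of 29 higher and 2 lower. The lower ones were GDF15 at -1.74, from discordant probes at -3.16 and -0.31, and PLK3 at -1.26. Histone genes had a median of -0.55 (-0.82 to 0.03, 19 genes), led by H4C8 at -2.20. H3K9 methylation enzymes and readers, a list that also holds demethylases (the KDM genes), had 1 of 16 genes past 2-fold, CBX1 at 1.05. Its median was 0.11 (-0.05 to 0.54). The H3K9 methyltransferases EHMT1 and EHMT2 were at 0.33 and 0.61. Lists of TGF-beta and BMP targets (median 0.15, -1.22 to 0.61) and of Wnt and Notch genes (median -0.12, -0.38 to 0.64) had members past 2-fold in both directions, including INHBA at -3.58 and SFRP1 at 2.10. The TGF-beta and Wnt lists had means of -0.18 and 0.13, opposite in sign to their medians.

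The second comparison asked how FZR1-depleted senescent cells differed from senescent cells with a control siRNA. The lowest genes were largely those of the inflammatory secretome. CXCL8 was 39.8-fold lower in the depleted cells, IL1B 29.8-fold, CXCL3 26.5-fold, CXCL10 24.7-fold, IL6 19.9-fold and CXCL2 17.4-fold, and CXCL1 was at -4.09. The serpin SERPINB3 was 25.7-fold lower, the hyaluronan synthase HAS2 13.4-fold and BCL2A1 11.7-fold. In all, 701 of 12169 genes were at least 2-fold higher after depletion and 559 at least 2-fold lower.

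Of 23 measured SASP cytokines and chemokines, 14 were at least 2-fold lower after depletion, 0 were 2-fold higher and 21 lay below 0 (median -2.28, -3.38 to -0.65). IL1A was 7.64-fold lower and CCL2 7.45-fold lower. CXCL1, CXCL2 and CXCL3 are close paralogs, so their probes may share signal. SASP growth factors and proteases had 12 of 28 lower and 2 higher (median -0.56, -1.46 to 0.12). The hormone STC1 was at -3.53, NRG1 at -2.91, MMP3 at -2.20, FGF2 at -2.19 and MMP1 at -1.98, the last from probes at -1.50 and -2.46. NF-kB targets had 12 of 25 lower and 0 higher (median -0.82, -1.49 to -0.43), with PTGS2 at -2.80, the NF-kB feedback inhibitor TNFAIP3 at -2.57 and TRAF1 at -2.56. The medians of the 3 lists lay below those of all 10000 random lists.

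**Figure D1:**
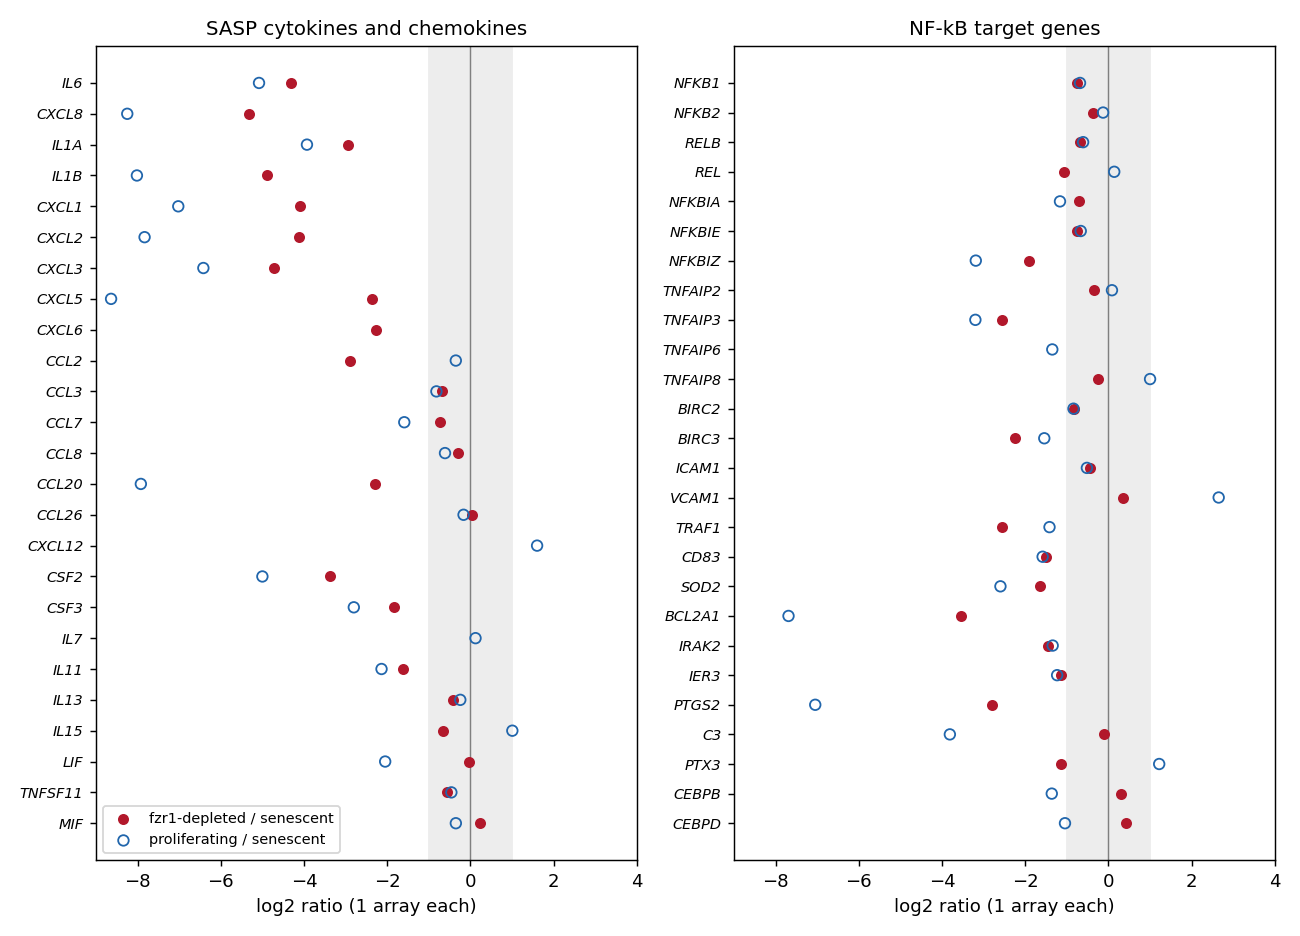
Log2 ratio to senescent cells (x axis) of each SASP cytokine or chemokine and each NF-kB target (y axis) with a value, 1 array per comparison and no error bar; filled points are FZR1-depleted cells, open points proliferating cells, and the grey band is under 2-fold. CXCL8, IL1B and IL6 lie far below 0 in both, at -5.31, -4.90 and -4.31 after depletion.

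Cell-division genes, already lower in senescent than in proliferating cells, were lower again after FZR1 depletion. In the G2/M and mitosis list, 14 of 24 measured genes were at least 2-fold lower and none was 2-fold higher (median -1.09, -1.74 to -0.23). PRC1 was at -2.85, CDK1 at -2.75, the survivin gene BIRC5 at -2.25 and TOP2A at -1.93. Known APC/C-Cdh1 substrates had 13 of 29 lower and 0 higher (median -0.73, -1.51 to -0.24), with CDC20 at -2.73 and CCNA2 at -1.83. The substrates SKP2 at 0.90, CCNB1 at -0.18, AURKA at -0.17 and GMNN at -0.15 lay within 2-fold, as did MKI67 at 0.61. DNA replication and G1/S genes had 6 of 34 lower and 1 higher (median -0.38, -0.70 to -0.15). UHRF1 was at -2.04, TK1 at -1.66 and MCM6 at -1.46, and PCNA was the higher one at 1.71. Homologous recombination and Fanconi genes had 2 of 10 lower (median -0.44, -1.33 to 0.26), BARD1 at -1.47 and FANCI at -1.33. Null cells were common here: 45.5% of the G2/M list and 47.4% of the recombination list had no value on this array, against 30.7% of all genes. PLK1 and EHMT2 were among the genes without one.

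p53 target genes were higher after depletion, with 10 of 29 at least 2-fold higher and 2 lower (median 0.54, 0.19 to 1.14, above 99.98% of random lists). The antiproliferative gene BTG2 was 12.9-fold higher, SESN1 at 2.24, the pro-apoptotic BBC3 at 1.83 and CCNG1 at 1.69. CDKN1A was at -0.45. GDF15 was at -1.65, from only the probe that was at -3.16 in proliferating cells. The list of senescence cell-cycle inhibitors, which also holds LMNB1 and GLB1, had a median of 0.34 (-0.94 to 0.95, 10 genes). The inhibitors CDKN1B, CDKN2B and CDKN2D were at 2.11, 0.44 and -1.02, and LMNB1 and GLB1 at -0.94 and 0.95. The highest genes after depletion were FOS, an AP-1 transcription factor, at 32.3-fold, the chemokine receptor CXCR4 at 27.7-fold, the melanocyte enzyme gene TYRP1 at 23.4-fold and the prostaglandin transporter SLCO2A1 at 19.7-fold. LIPH was 18.8-fold higher, TEX29 13.3-fold, SPNS2 11.3-fold and the orphan nuclear receptor NR4A2 10.7-fold, and CYTL1 was at 3.70. Ras-MAPK response genes had 4 of 31 higher and 4 lower (median -0.08, -0.28 to 0.20, mean 0.10), with EPHA4 at 2.03, DUSP6 at -1.27 and HRAS at -1.45.

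Interferon response genes were lower after depletion, with 11 of 28 at least 2-fold lower and 0 higher (median -0.61, -1.13 to -0.13, below all 10000 random lists). After CXCL10, the lowest were the immunoproteasome subunit PSMB9 at -1.97, IFI35 at -1.66 and IFI44 at -1.62. Collagens and fibrillar matrix genes had 9 of 33 higher and 1 lower (median 0.51, 0.0032 to 0.88, above 99.99% of random lists). VCAN was at 2.74, COL1A2 at 2.25, COL1A1 at 1.94 and COL5A1 at 1.57. Contractile genes (median -0.16, -0.63 to 0.23, 15 genes) and fibroblast identity genes (median -0.15, -0.44 to 0.24, 20 genes) did not stand apart from random lists, with ACTG2 at -1.28, PRRX1 at -1.43 and vimentin (VIM) at -1.79. Histone genes had no member past 2-fold (median 0.38, -0.25 to 0.62, 17 genes). H3K9 methylation enzymes and readers had the demethylase KDM3A at 1.39 as the only one of 15 past 2-fold (median 0.35, -0.01 to 0.72). The methyltransferase EHMT1 was at -0.15. As the list pools methyltransferases, demethylases and readers, its median gives no direction for methylation. APC/C subunits and regulators had 3 of 21 higher and 4 lower (median 0.08, -0.85 to 0.51, mean -0.14), including CDC23 at 1.53 and ANAPC13 at -1.69. TGF-beta and BMP targets had a median of 0.30 (0.04 to 0.74, 17 genes) with BMP4 at 1.74 and ID1 at -1.80. Wnt and Notch genes had a median of 0.27 (-0.50 to 1.01, 16 genes) with SFRP1 at 2.06 and HES1 at 1.64.

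**Figure D2:**
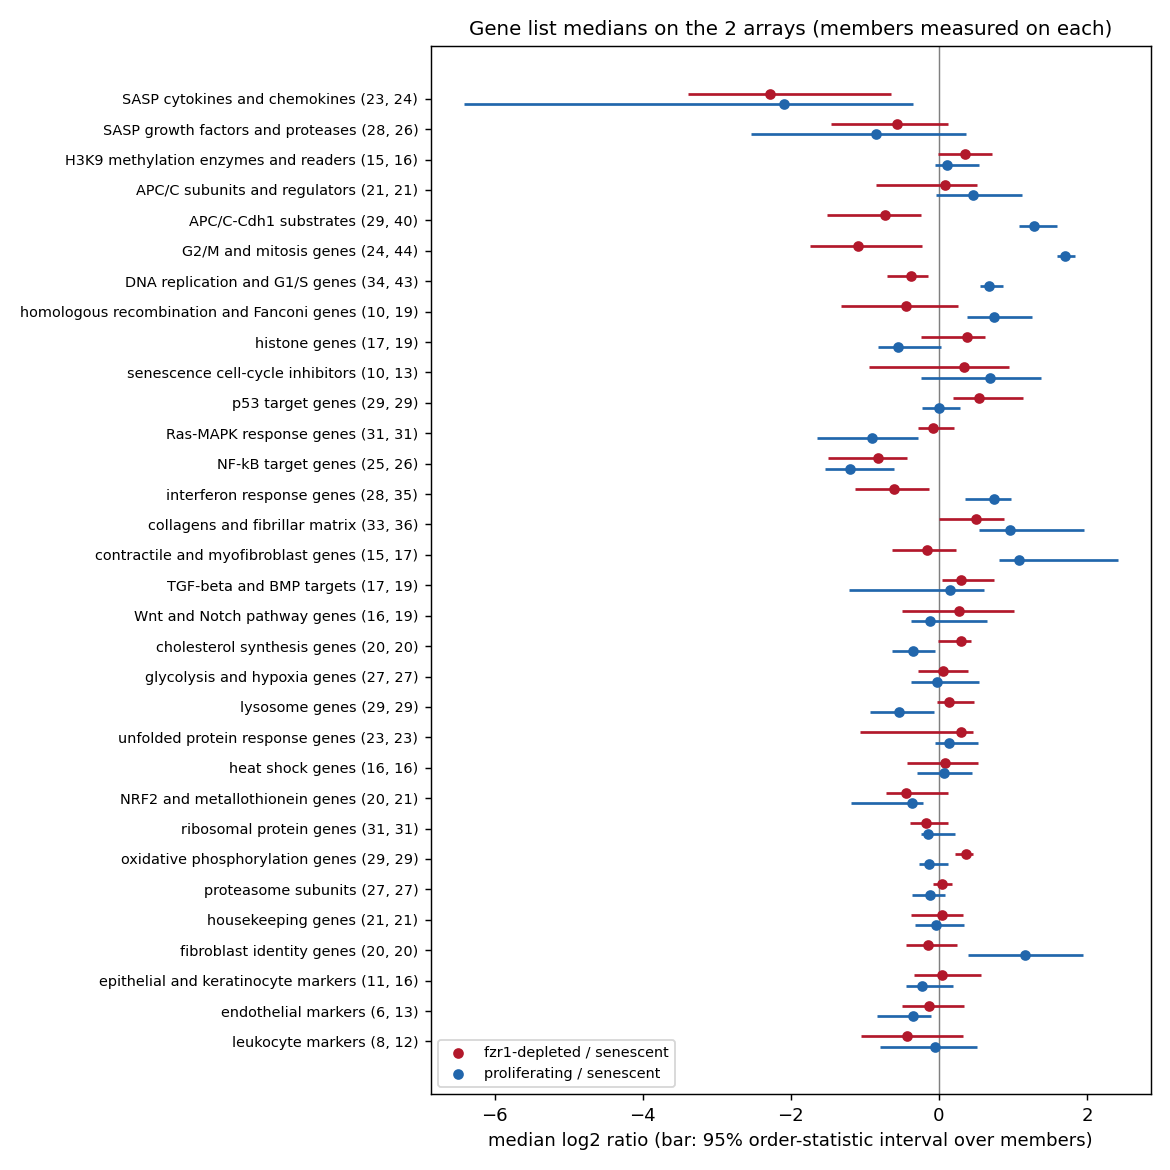
Median log2 ratio to senescent cells (x axis) of each fixed gene list (y axis, with the members measured on the FZR1-depleted and proliferating array in brackets), red for FZR1-depleted and blue for proliferating cells; bars are 95% order-statistic intervals over members, not replicate error. SASP cytokine medians lie below 0 on both arrays (-2.28 and -2.09), and G2/M medians on opposite sides (-1.09 and 1.70).

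Markers of other cell types were mostly within 2-fold, and fewer of them were measured on the FZR1-depleted array. On the FZR1-depleted array the medians were 0.04 for epithelial and keratinocyte markers (-0.33 to 0.57, 11 genes), -0.13 for endothelial markers (-0.51 to 0.34, 6 genes) and -0.44 for leukocyte markers (-1.05 to 0.32, 8 genes). On the proliferating array they were -0.22 (-0.45 to 0.19, 16 genes), -0.35 (-0.83 to -0.11, 13 genes) and -0.05 (-0.79 to 0.51, 12 genes). The leukocyte median after depletion (percentile 1.18, 7 of 8 genes below 0) and the endothelial median in proliferating cells (percentile 0.97, 12 of 13 below 0) lay below the central 95% of random lists, on the same side of 0 as the SASP cytokine medians. KRT17 was at 1.40 after depletion, and TEK was at 2.41 and KRT7 at -1.54 in proliferating cells. Housekeeping genes had medians of 0.03 (-0.38 to 0.32) after depletion and -0.04 (-0.33 to 0.34) in proliferating cells, with 21 genes measured and means of -0.05 and 0.06, opposite in sign to the medians.

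The third comparison asked which genes that separate senescent from proliferating cells lay nearer the proliferating level after FZR1 depletion. Over 12114 genes measured on both arrays, 130 were at least 2-fold lower on both and 115 at least 2-fold higher on both. A further 66 were lower after depletion and higher in proliferating cells, and 53 were higher after depletion and lower in proliferating cells. Independent lists would give 23.7, 40.3, 33.0 and 29.0 genes in these 4 classes. Over 100 simulations with the correlation set to 0.5, the averages were 123 (101 to 143), 180 (155 to 210), 0.92 (0 to 3) and 0.68 (0 to 3) genes. That correlation holds for 3 RNAs of equal spread with no shared effect and 1 senescent extract on both arrays. The labels do not settle whether the extract was shared, and a senescent RNA of another spread would give other counts. The number lower on both lay within the simulated range and the number higher on both lay below it, while both counts in opposite directions lay above the simulated and the independent values. The simulation thus does not describe the data as a whole, and part of the same-direction excess over independent lists may come from a shared senescent RNA. The senescent RNA also carried the same dye on both arrays, and without a dye swap an effect of the dye could not be separated. Across genes, which are not independent replicates, Pearson's r was 0.236 and Spearman's rho 0.216. The simulated r was 0.460 and the largest r that a shared RNA alone can give was 0.877. The covariance was 0.115, against 0.243 from a shared RNA under equal spreads, and without replicates the true spread of the senescent RNA is unknown. All of these values rest on the likely direction of both arrays: if 1 array alone ran the other way, the 245 genes in the same and the 119 in opposite directions would exchange and r would change sign.

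Of the 519 genes at least 2-fold lower in proliferating cells, 336 (64.7%) lay below 0 after depletion, against 48.4% of all genes. Of the 722 genes at least 2-fold higher in proliferating cells, 423 (58.6%) lay above 0, against 51.6% of all genes. The same simulations, with the correlation set to 0.5, gave 87.6% (83.8% to 90.0%) and 87.8% (85.2% to 90.4%), and the observed shares lay outside these ranges. These ranges belong to that setting, and a shared senescent RNA of another spread would give other shares. Whether the observed shares hold a common effect was left open, as the model needs 1 shared extract and its true spread is unknown. With the FZR1-depleted array turned they would be 35.3% and 41.4%, against 51.6% and 48.4% of all genes. The 10 genes with the largest values in the same direction were all lower on both arrays. They were CXCL8, IL1B, CXCL3, IL6, CXCL2, CXCL1, BCL2A1, the colony-stimulating factor CSF2 (-3.38 and -5.00), LCE2C (-3.23 and -5.97) and CBLN2 (-3.04 and -3.87). Their levels after depletion remained above the proliferating level in the indirect comparison, by 7.65-fold for CXCL8, 8.68-fold for IL1B and 1.70-fold for IL6. For the SASP cytokine list the FZR1-depleted value exceeded the proliferating value by a median of 0.91 (0.21 to 2.93, 22 genes), and for NF-kB targets by 0.02 (-0.25 to 0.63, 25 genes).

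The largest genes in opposite directions included ESM1, an endothelial proteoglycan gene, at 2.20 after depletion and -4.03 in proliferating cells, CES1 at 2.04 and -4.29, CST1 at 1.94 and -5.72, TSGA10 at 2.05 and -2.42, and ABCA3 at 1.78 and -2.16. In the other direction were CDK1, TOP2A, HJURP at -1.83 and 1.77, the angiopoietin ANGPT1 at -2.00 and 2.44 and PSIP1 at -1.80 and 1.93. In the G2/M list 19 of 24 genes measured on both arrays had opposite signs, and the depleted value lay below the proliferating one by a median difference of -2.56 (-3.48 to -1.58). For the substrate list the difference was -1.67 (-2.70 to -0.86), for interferon genes -1.37 (-1.87 to -0.50), for contractile genes -1.24 (-2.37 to -0.52) and for collagens -0.61 (-1.54 to 0.15). Ras-MAPK response genes differed by 0.79 (0.22 to 1.31) and p53 targets by 0.65 (0.31 to 0.95).

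**Figure D3:**
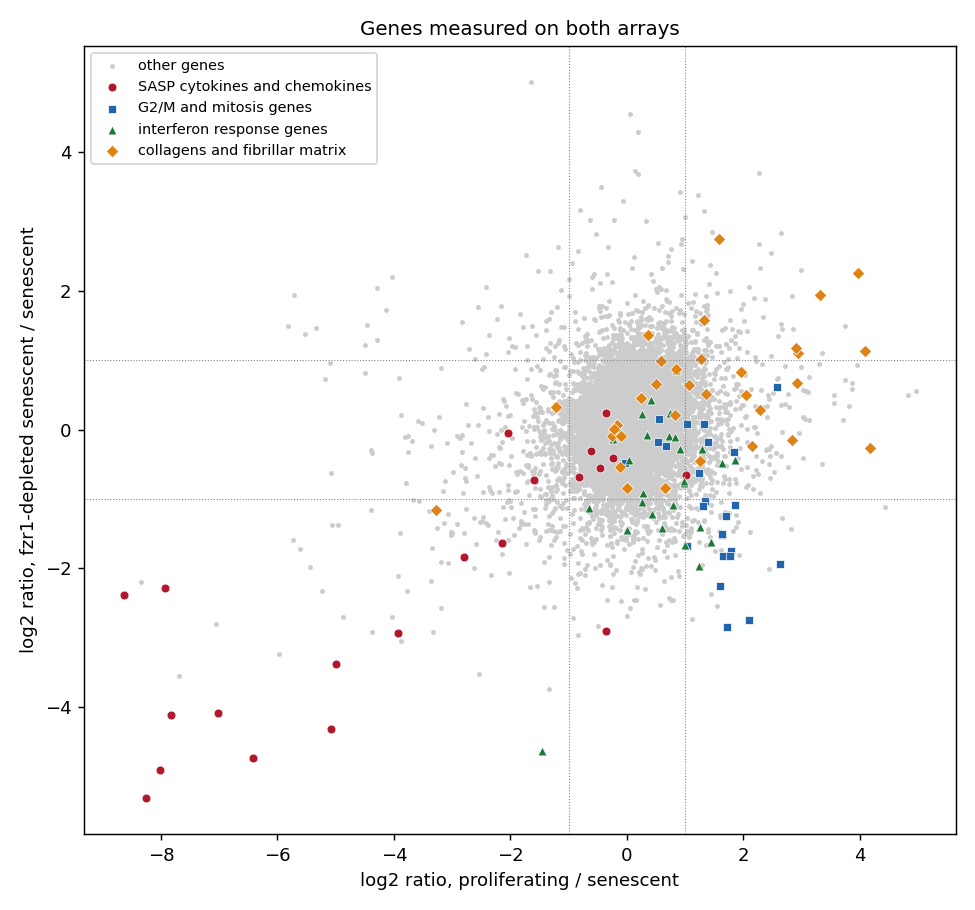
Log2 ratio of each gene measured on both arrays, proliferating over senescent (x axis) against FZR1-depleted over senescent (y axis), 1 array each, with 4 fixed lists marked and dotted lines at 2-fold. SASP genes reach the lower left, with CXCL8 at -8.25 and -5.31, while G2/M genes such as CDK1, at 2.10 and -2.75, lie at the lower right.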

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

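The tests of explanations in this part were chosen after the list medians had been seen, except that of dim probes against the G2/M list, which was fixed before its value was known. There were 4 gene lists whose medians lay on opposite sides of 0 on the 2 arrays, with both intervals clear of 0. Their FZR1-depleted minus proliferating medians were -2.56 for G2/M and mitosis genes, -1.67 for APC/C-Cdh1 substrates, -0.92 for DNA replication and G1/S genes and -1.37 for interferon response genes. With 1 array each, these differences were not tested against replicate error.

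The lower level of cell-cycle transcripts after FZR1 depletion runs against a simple return to the proliferating state. The G2/M median was 1.70 in proliferating cells and -1.09 after depletion. Cdh1 targets proteins of this class for degradation, but protein levels were not measured. A bias of dim probes was tested on 691 measured probes whose sister probe for the same gene was null on the FZR1-depleted array. Their median was -0.16 (-0.21 to -0.13), so these probes themselves lay slightly below 0. It was above the intervals of the G2/M list (upper bound -0.23) and of the substrate list (-0.24), both narrowly. It was not above that of the DNA replication list (-0.15). A bias of the size seen in these probes thus falls short of the G2/M and substrate medians. Without signal values, these probes are not shown to be as dim as those of the lists. A larger bias of dim probes therefore stays open for all of these lists. An unusual senescent control RNA remains open too, as the G2/M median of -1.09 rests on 1 senescent RNA, and whether the other array held the same extract is not given in the sources used here. An effect of FZR1 depletion itself is a candidate explanation that the design names and a single array cannot test.

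The lower level of SASP and NF-kB transcripts might come from escape of cells from senescence, from lower Ras signalling or from an unusual senescent control RNA. Escape would bring the cell-cycle transcripts of dividing cells, but the G2/M median was -1.09 (-1.74 to -0.23). Of 24 measured genes 20 lay below 0 and 4 above, while 20 of the 44 on the chip had no value. This argues against escape only as far as that median can be trusted. A larger bias of dim probes and an unusual senescent RNA were left open for it above. HRAS was 2.73-fold lower after depletion, close to its 2.46-fold difference in proliferating cells. Its transcript level does not measure Ras activity, which OHT switches on in the fusion. Lower Ras signalling was therefore tested on 27 Ras-MAPK genes outside the SASP and NF-kB lists, without HRAS. Their median was 0.034 (-0.28 to 0.29) after depletion and -0.86 (-1.65 to -0.05) in proliferating cells. The written criterion against this explanation asked for a lower bound after depletion above the upper bound in proliferating cells. It was not met, as the intervals overlap, so the test left lower Ras signalling undecided. Gene by gene the depleted value was higher by 0.79 (0.22 to 1.31), a comparison outside that criterion. For these genes it goes against a full drop of Ras signalling to the proliferating level. A partial drop stays open, since the interval after depletion reaches below 0. A bound of -0.54, set after the values were seen, is not used. It came from the 28 SASP and NF-kB genes selected for being at least 2-fold lower in proliferating cells. An unusual senescent RNA stays open too, beside an effect of the FZR1 siRNA, since the SASP median of -2.28 has no second senescent culture behind it.

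For the interferon genes, the labels number the control siRNA of the proliferating cells differently from that of the senescent cells. A different control oligo may therefore contribute to the median of 0.74 (0.35 to 0.98) in proliferating cells. It cannot be told apart from growth state or OHT, because all of these change together on that array.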

How the results depend on the processing

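The natural logarithm, the turned direction and all alternatives for the sign shares were chosen after seeing the data, and the others before. Counts of genes moved with the threshold by construction. At 1.5-fold, 2127 genes were higher and 1464 lower after FZR1 depletion, 2551 higher and 1612 lower in proliferating cells, and 893 genes passed on both arrays in the same and 420 in opposite directions. At 3-fold these counts were 157, 168, 367, 254, 59 and 21. If the deposited values were natural logarithms, 2-fold would correspond to 0.693 and the counts would be 1643, 1138, 2033, 1216, 620 and 286. Restricting the proliferating array to genes measured on both arrays left 722 genes higher in place of 1117, since 4617 probes had a value on that array alone, 551 of them at least 2-fold higher and 138 lower. Pearson's r was 0.182 without genes past 3-fold on either array, by construction a narrower range, and Spearman's rho stayed within its interval. Apart from the turned direction, the other counts and correlations stayed within 1.5 times or within their interval under both centrings, the most extreme probe, one robust SD and the removal of the cell-cycle lists, where each applied. Housekeeping centring shifted the arrays by 0.03 and -0.04. None of the 33 list medians outside the central 95% of random lists, and none of the 15 list differences clear of 0, changed sign or left its interval under the alternatives run for it. Centring and the most extreme probe could change little here. The column medians were already -6e-06 and 1.6e-05, and 2560 of 17559 genes had 2 or more probes. Of 476 values of named genes, 14 moved by more than the probe SD with the most extreme probe. Among the values of at least 2-fold, 0 changed sign, while smaller values, some of them close to 0, were not checked for sign. The most extreme of 2 probes has the sign of their mean by construction. Turning the direction was planned only if FZR1 had gone against its label or the arrays had correlated below -0.3, which they did not. With the FZR1-depleted array alone turned, by construction, 119 genes passed in the same and 245 in opposite directions, Pearson's r was -0.236, Spearman's rho -0.216 and the sign shares 35.3% and 41.4%. Under both centrings and the most extreme probe the sign shares stayed within their 95% binomial intervals. Signal over background is unknown, so which low-signal ratios are unreliable could not be assessed.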

Other observations

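Lysosome genes were lower in proliferating cells (median -0.54, -0.93 to -0.07, 7 of 29 at least 2-fold lower), led by cathepsin S (CTSS) at -4.39 and the cholesterol transporter NPC1 at -1.97. After FZR1 depletion the lysosome median was 0.14 (-0.03 to 0.47), with CTSK at -2.71, CTSL at -1.79 and FUCA1 at 2.29. Oxidative phosphorylation genes had a median of 0.37 after depletion (0.22 to 0.46, 24 of 29 above 0) and -0.13 in proliferating cells (-0.27 to 0.12). Cholesterol synthesis genes had medians of 0.30 (-0.01 to 0.44) after depletion and -0.36 (-0.64 to -0.06) in proliferating cells. NRF2 and metallothionein genes had medians of -0.45 (-0.72 to 0.13) and -0.37 (-1.18 to -0.22), with haem oxygenase HMOX1 at -2.67 and MT2A at -2.42 in proliferating cells and the ferritin chain FTL at -1.73 after depletion.

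Unfolded protein response genes split after depletion, with a median of 0.30 (-1.07 to 0.46), a mean of -0.22, 7 of 23 at least 2-fold lower and 2 higher. The lower ones included the amino acid response genes ASNS at -1.80 and CHAC1 at -1.64, beside the chaperones PDIA4 at -2.17 and CANX at -1.62, while HSPA5 was at 1.24. In proliferating cells the list's median was 0.13 (-0.06 to 0.52). Medians after depletion and in proliferating cells were 0.05 (-0.28 to 0.40) and -0.03 (-0.38 to 0.54, mean 0.11) for glycolysis and hypoxia genes, with NDRG1 at 2.20 after depletion, and 0.08 (-0.43 to 0.53) and 0.07 (-0.30 to 0.45) for heat shock genes. They were -0.18 (-0.39 to 0.12) and -0.15 (-0.24 to 0.22) for ribosomal protein genes, and 0.04 (-0.08 to 0.18) and -0.12 (-0.37 to 0.09) for proteasome subunits.

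Of the probes without a gene symbol, 65 of 2138 were at least 2-fold higher and 54 lower after depletion, against 701 and 559 of 12169 genes. In proliferating cells 112 of 3198 were higher and 82 lower, against 1117 and 617 of 15111 genes. Values on the FZR1-depleted array alone were given by 75 probes, of which 29 were at least 2-fold higher and 9 lower.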
